A study of Rattus norvegicus with 12 samples.

How the data were processed

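Soleus muscles of 6 female Wistar rats were profiled on radioactively labelled expression arrays, 1 array per muscle and 2 muscles per rat. Per the labels, total RNA (3 µg) was reverse transcribed with gene-specific primers and labelled with 32P-dATP. The deposited table holds 1 intensity per probe for 1185 probes on each of the 12 arrays, as positive numbers with 1 decimal. The scanner, the image analysis, the handling of background and the array design are not given in the sources used here. The deposited intensities were linear and not scaled to a common median, since the array medians differed by up to 7.46-fold. They carried a floor well above 0 on every array, so no background appeared to have been subtracted by the authors before deposit. No scanner output was used here for comparison, so whether any other step was applied before deposit stays unknown. Each value is the level of one array, so no ratio direction had to be settled.

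The deposited probe identifiers consist of a letter code and a number, and the table does not pair them with genes. None (0 of 1185) matched an entry of the rat gene table used for names (assembly GRCr8). All results are therefore given by probe, and the 25 gene lists fixed before the data were examined (contractile, mitochondrial, adhesion, matrix, signalling and cell type lists) could not be tested, so 0 lists were tested. For the same reason the level of the transferred gene could not be used to check the labels. The naming rule fixed beforehand asked for probes with a single gene symbol, ranked by the size of the change past the threshold and filled up by the smallest unadjusted p. With no symbols, the 2 probes higher and the 2 probes lower in FAK muscles with the smallest unadjusted p are named instead, a restriction made after the probe identifiers were seen.

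Groups were taken from the sample titles, which give the construct and the rat number. The series' design text describes a paired comparison between the legs of one animal, so the rat was a block in the main model. The pairing was checked on the arrays: the deviations of the FAK and the empty-vector muscle of one rat from their group means correlated with r between 0.36 and 0.61 across probes in the 6 rats. Of the 6 FAK arrays, 5 correlated best with the empty-vector array of the same rat.

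Because the medians differed, the arrays were quantile normalized on the log2 scale, as fixed beforehand. A pseudocount of 1574, the value at percentile 10 of all deposited intensities, was then added and log2 taken. All differences are on this log2(value + pseudocount) scale with the floor left in. It understates changes in the signal above the floor, most strongly those of dim probes. All 1185 probes had a value in both muscles of all 6 rats and were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. Single values over the 6 rats were tested with an exact two-sided sign-flip permutation test, whose smallest possible p is 0.03125. The whole-profile shift was taken from the deposited values before any scaling. The number of arrays limits the precision, and with no replicate arrays of one muscle the spread between rats includes technical error.

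Alternatives fixed beforehand were the fit without the block, the rat as a random block, the deposited values without scaling, scaling to the array median, other pseudocounts, a filter on dim probes, each rat left out in turn, moderation with a trend, array weights and the exact test per probe. Chosen after seeing the data were normexp background correction (offset 50) with quantile or median scaling, total intensity scaling, cyclic loess, no pseudocount, and the fit without rat 425 under other scalings. The pipeline was tested on simulated data with 1185 probes, of which 200 were changed in the signal above the floor. Each probe kept its fitted level per rat, the same in both legs before the change, and its residual spread in the log2 values before scaling. That spread includes brightness differences between the 2 arrays of a rat, which scaling could not remove from the simulated data. Over 20 simulated sets, 79.1% of the 2-fold and 93.1% of the 4-fold changes were called among probes above 2 times the floor. Among dimmer probes 47.5% of the changes were called. Unchanged probes made up 6.99% of the calls. Among the probes above 2 times the floor, a simulated 4-fold change (2 on the log2 scale) was estimated at a median of 1.13. With no change, 0.05 probes per set were called. The simulated noise was independent between probes, unlike that of real probes on one array, so these rates need not carry over.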

Results

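The study compared soleus muscles that received a focal adhesion kinase (FAK) expression construct with muscles that received the empty vector. FAK is a tyrosine kinase at integrin adhesion sites, and the soleus is a slow postural muscle of the calf. Both constructs were driven by the CMV promoter and delivered by electro-transfer, 1 to each leg of a 3-month-old rat. Hindlimb suspension began 2 days later and unloaded the muscles for 7 days, after which the rats walked freely for 5 days before the muscles were collected. There were 6 FAK and 6 empty-vector muscles from the same 6 rats, numbered 424, 425, 426, 434, 435 and 436.

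Each array reported 1185 probes. The total deposited intensity ranged from 4315371 to 57484637 units per array. The median intensities of the FAK arrays were 7862, 6910, 6530.5, 12814.8, 1718.8 and 1743.6 in rats 424, 425, 426, 434, 435 and 436. Those of the empty-vector arrays were 6447.5, 7468.1, 6657.3, 11482.7, 1779.2 and 1717.3 in the same order. Brightness thus differed between rats far more than between the legs of one rat, and each level of brightness held both vectors. Most probes lay close to the array's floor, taken as its percentile 1. Between 212 and 589 probes per array, or 17.9% to 49.7%, exceeded 2 times that floor. The brightest 5 probes carried between 20.5% and 33.2% of an array's total.

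**Figure D1:**
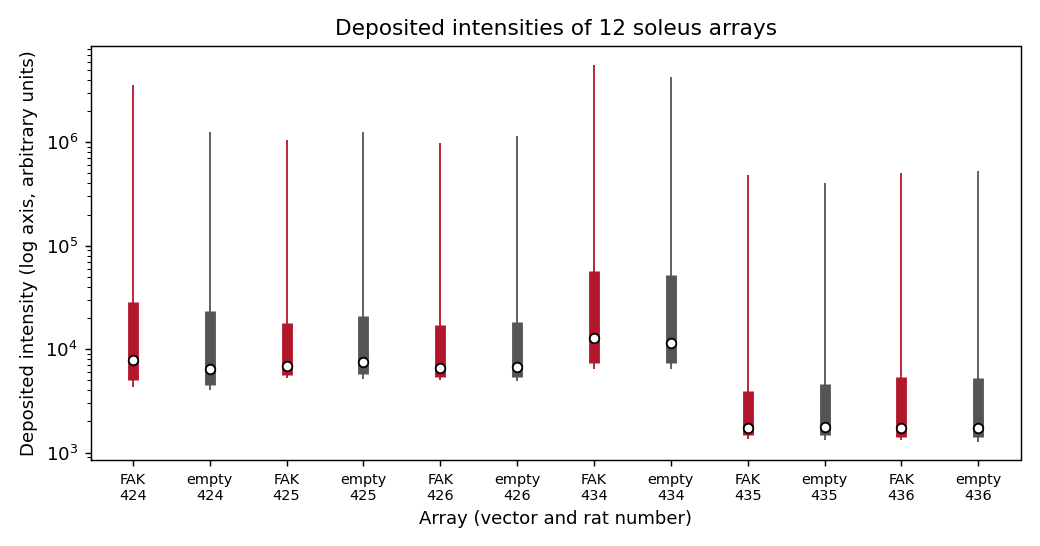
Deposited intensity (arbitrary units, log axis) of each of the 12 arrays, FAK in red and empty vector in grey. Thin lines run from percentile 1 to the maximum, thick bars from percentile 10 to 90, and circles mark medians, which lie between 1717.3 and 12814.8 and are close within each rat.

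The first question was whether the whole profile shifted with the FAK construct before any scaling. The median probe differed between the FAK and the empty leg by 0.018 ± 0.086 on the log2 scale (SD, n = 6). It was higher in the FAK leg in 3 of 6 rats (exact sign-flip permutation p = 0.6875, two-sided). No shift larger than the spread between rats was detected. The array median lay at only 1.26 to 1.99 times the floor, so this comparison says little about the brighter probes.

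The main comparison asked which transcripts differed between the FAK and the empty leg of the same rat. Of the 1185 probes, 1 passed adjusted p 0.05 in the paired limma fit, and it was higher in FAK muscles. This probe, RG339, is among the 6 brightest on all 12 arrays, at 80.2 to 874 times the array's floor. Its level was higher in the FAK leg by 0.95 on the log2 scale (SE 0.10, n = 6 rats), or 1.94-fold, with a limma adjusted p of 0.022. After quantile normalization the difference was positive in 6 of 6 rats, from 0.64 to 1.27. Quantile normalization replaces each value by the mean for its rank, which is coarse among the 6 brightest probes, and rats 424 and 436 got the same difference of 1.27. The SD over the 6 rats was 0.29 after this step, against 0.93 after scaling to the array median and 0.86 after cyclic loess, so the SE of 0.10 does not show how closely the rats agreed. At the deposited scale, RG339 stood at 451 times the array median in the FAK leg of rat 424 against 123 times in its empty leg. In rats 434, 435 and 436 it stood at 439, 281 and 288 times the median in the FAK leg against 161, 89.0 and 108 times in the empty leg. In rat 426 the values were 147 and 99.0 times. In rat 425 the order was the other way, with 60.9 times in the FAK leg and 93.6 times in the empty leg.

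The RG339 differences of single rats therefore depended on the scaling. In rat 435 it was 0.72 after quantile normalization, 1.66 after scaling to the array median and 1.95 after cyclic loess. In rat 425 it was 0.64 after quantile normalization, -0.62 after scaling to the array median, -0.44 after scaling to the total and -0.15 after cyclic loess. Scaled to the median, RG339 was higher in FAK by 1.06 on average over the 6 rats, with an adjusted p of 0.16 in limma. The call was also lost in the limma fit without the pairing by rat (adjusted p = 0.32). It was lost when rat 424, 426, 434 or 436 was left out as well (limma adjusted p between 0.070 and 0.17), and kept without rat 425 (1.06 on the log2 scale, adjusted p = 0.0089) or rat 435 (0.91, adjusted p = 0.034).

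The next probe higher in FAK muscles, RG325, differed by 0.55 on the log2 scale (SE 0.090), or 1.46-fold, and was higher in 6 of 6 rats (limma adjusted p = 0.15). The lower probes with the smallest p were R344 and RG389. R344 differed by -0.27 on the log2 scale (SE 0.041) and was lower in 6 of 6 rats (limma adjusted p = 0.14). RG389 differed by -0.35 (SE 0.065) and was lower in 6 of 6 rats (limma adjusted p = 0.15). None of these 3 probes passed the threshold in the main fit. After scaling to the total, chosen after seeing the data, all 3 did (limma adjusted p 0.022 for RG325, 0.032 for R344 and RG389). That total includes the bright RG339, so a higher RG339 lowers the other scaled values of its array. RG325 in rat 425 also depended on the scaling, at 0.13 after quantile normalization and -0.036 after scaling to the array median. Each of the 3 had an exact sign-flip permutation p of 0.03125, the smallest that 6 rats allow. This p is unadjusted and adds little, since the probes were picked for a small limma p over the same rats. These 3 probes were measured above the floor, at 2.16 to 15.0 times its value. The floor and the pseudocount shrink their differences. After normexp with quantile normalization these were 0.73 for RG325, -0.43 for R344 and -0.47 for RG389, and none passed the threshold.

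Rats were also grouped by the brightness of their arrays. On the quantile normalized values, where each of the 4 probes went one way in all 6 rats, only the sizes could differ. RG339 was higher in FAK by a mean of 0.88 in the 3 rats with array medians between 6447.5 and 7862, by 1.11 in the single rat with brighter arrays and by 0.99 in the 2 rats with dimmer arrays. For RG325 the corresponding means were 0.51, 0.45 and 0.66. R344 gave -0.33, -0.29 and -0.17, and RG389 gave -0.35, -0.26 and -0.39. These sets held 1 to 3 rats each and were not compared by a test.

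**Figure D2:**
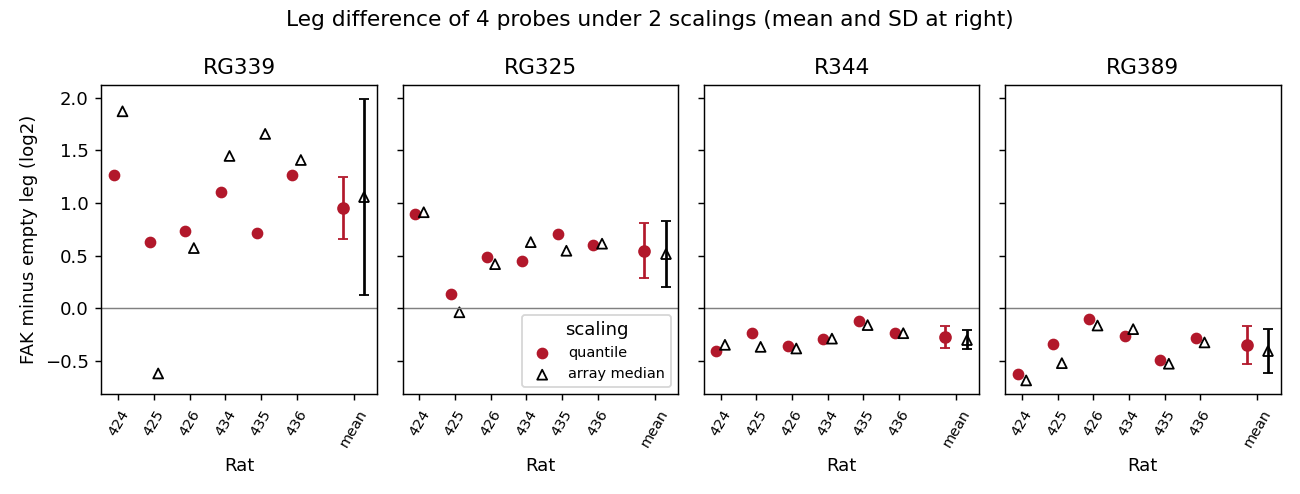
FAK leg minus empty leg (log2) for probes RG339, RG325, R344 and RG389 in each of the 6 rats, after quantile normalization (filled circles) and after scaling to the array median (open triangles), with mean and SD over rats at the right of each panel. RG339 in rat 425 lies at 0.64 under the first scaling and at -0.62 under the second.

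Below the threshold, small p-values were more frequent than expected for independent probes with no difference. At an unadjusted p under 0.05, limma gave 204 probes, 98 higher and 106 lower in FAK muscles, where 59.3 would be expected by chance. The median size of these 204 differences was 0.15 on the log2 scale, and 1 of them exceeded 1. Of the 204 probes, 99 had a mean within 1.5 times the floor (pseudocount added to both), against 761 of all 1185. In 38 probes the FAK leg was higher in all 6 rats, and in 58 it was higher in none, 96 in all. The 58 include probes with a difference of 0 in some rats, such as R371, so fewer than 58 were lower in all 6. Independent random signs without ties would give 37.0 probes with all 6 rats one way (3.125%). The 96 therefore overstate the excess, and probes on one array are not independent.

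The rats differed in how far they shared these differences. Across all 1185 probes, the leg differences of rats 424, 426, 434, 435 and 436 correlated positively in all 10 pairs, with a mean r of 0.48 and a range from 0.26 to 0.72. The differences of rat 425 correlated negatively with each of the other 5, from -0.33 to -0.15. The slope of its differences on the mean of the other 5 rats was -0.32. The same slope was 0.37 to 1.58 for the other rats, so the reversal in rat 425 was weak. These correlations are across probes, which are not independent replicates. After background correction by normexp and quantile normalization, the mean r of rat 425 with the others was -0.035, against 0.096 to 0.29 for the other rats.

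**Figure D3:**
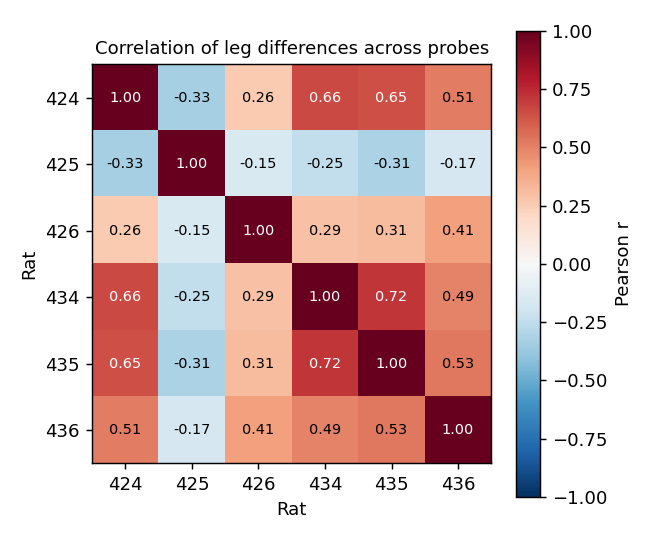
Pearson r between rats of the FAK minus empty leg differences (log2, quantile normalized) across 1185 probes, with rats on both axes and r given in each cell. The row and column of rat 425 hold negative values (-0.33 to -0.15), and the other rats lie between 0.26 and 0.72 with each other.

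Leaving out each rat in turn was planned, and the number of changed probes depended on which rat it was. Without rat 425, 52 probes passed adjusted p 0.05 in limma, 34 higher and 18 lower in FAK muscles of the remaining 5 rats. Without rat 435 the count was 1, and without rat 424, 426, 434 or 436 it was 0. At an unadjusted p under 0.05 these fits gave between 125 probes (without rat 435) and 272 (without rat 425). All 52 probes moved one way in all 5 rats, which their selection by a fit on these same rats favours. Their differences ranged in size from 0.18 to 1.31 on the log2 scale with a median of 0.38, and 6 exceeded 1. In rat 425 itself, 38 of the 52 probes went the other way and 14 the same way. By size the differences there were small. Turned to the direction of the call, their median was -0.069 in rat 425, against 0.38 in the other 5 rats, which served to select them. When another rat was left out, 32 (rat 424) to 49 (rat 435) of the 52 top probes of that fit went the same way in it. With the other scalings, the fit without rat 425 called 41 probes after median scaling (24 higher, 17 lower), of which 37 were among the 52. It called 94 after scaling to the total (47 higher, 47 lower, 46 shared) and 19 after cyclic loess (15 higher, 4 lower, 19 shared). At an unadjusted limma p under 0.05, total scaling gave 77 higher and 177 lower probes, against 114 and 128 after median scaling. The total includes RG339, which may add to its lower calls and was not tested. The fit without rat 425 called 26 after normexp with quantile normalization (26 higher, 0 lower, 23 shared) and 28 after normexp with median scaling (27 higher, 1 lower, 26 shared). The lower calls were thus nearly all lost after background correction. At an unadjusted limma p under 0.05, these 2 normexp fits still gave 115 and 125 lower probes, against 139 after quantile normalization alone. RG339 was higher in FAK in each of these fits, by 1.06 to 1.49 on the log2 scale.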

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

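The tests of exchanged labels and of array contrast were chosen after the results were seen, as were the splits without rat 425, while the splits of all 12 arrays were planned. Of 19 sets of 6 values examined for a sample apart from the rest, 2 held one. Chance gives about 1 in 20 sets, so 2 of 19 is no clear excess. Both concerned rat 425.

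The first was the mean correlation of a rat's leg differences with those of the other rats. It was -0.24 in rat 425 and between 0.22 and 0.38 in the others after quantile normalization. It was -0.035 and -0.032 in rat 425 after normexp with quantile and with median scaling, against 0.084 to 0.30 in the others, so the opposition was close to 0 after background correction while rat 425 stayed the lowest. Contrast was measured as percentile 90 over percentile 10, and the FAK array had the lower contrast in rats 425, 426 and 435. On the quantile normalized values, lower contrast alone did not bring opposition. The log2 contrast difference was -0.19 in rat 435 and -0.20 in rat 425, yet rat 435 reached a mean correlation of 0.38. In rat 426 it was -0.095, with a mean correlation of 0.22, the lowest of the others. These rats are too few to exclude a part of contrast in the opposition. An exchange of the 2 legs' labels in rat 425 stays open, since each array's score along the FAK minus empty difference of the other rats decided neither way: over all probes the empty-vector array of rat 425 scored -0.29, between the other empty-vector arrays (-0.47 to -0.40) and the FAK arrays (-0.037 to 1.18). On the 52 probes called without that rat, which were selected because they separate the other rats' arrays, it scored -0.45, within the other empty-vector arrays (-0.57 to -0.38), and its FAK array scored below all of the other empty-vector arrays on both sets, at -0.61 and -0.73. A different response or transfer of the construct in rat 425, which the labels do not record, and array error in a single pair stay open as well and were not tested.

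The second was the level of RG339 in the FAK muscle of rat 425, at 19.08 on the log2 scale after quantile normalization, against 19.82 to 20.19 in the other FAK muscles. In that rat RG339 ranked position 4 from the top on the FAK array and position 6 on the empty-vector array. On the other FAK arrays it ranked position 1 or 2, and quantile normalization sets the level by this rank, so the gap of rat 425 depends on that step. Relative to the array median, RG339 was also lowest in rat 425 among the FAK arrays, at 60.9 times against 147 to 451 times.

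Swapping the legs of some rats gives 32 splits that keep the pairs. The count of 1 changed probe was reached in 3 of the 32, with 10 as the highest of the others, so chance cannot be excluded for it. The count of 204 probes at an unadjusted p under 0.05 was reached in 2 of the 32. The other was the split that swaps the legs of rat 425 alone, with 257 probes and also the 10 changed probes, so chance cannot be excluded here either. Without the pairing, 10 of 100 random splits of the 12 arrays gave at least the 123 probes of the real one, with 224 as the highest of the others. For the 52 probes called without rat 425, the 16 splits are too few for a share under 0.05. The real split (the only 1 of the 16 with as many) gave 52 and the highest other 0.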

How the results depend on the processing

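The number of changed probes was 1 in the main fit and depended on the settings. It was 0 for the values as deposited, after median scaling, after cyclic loess, after normexp with quantile or median scaling, without the replicate block, and with trend and robust moderation. It was 3 with array weights and 23 after scaling to the total. For the exact sign-flip permutation test per probe, 96 probes were higher in FAK in all 6 rats or in none, where 37.0 are expected by chance without ties. Fewer than these 96 reached its smallest p, since probes with ties, such as R371 (exact sign-flip permutation p = 0.0625), are among them. Leaving out 1 rat gave 0 to 52 probes. Without rat 425, the counts were 41, 94, 19, 26 and 28 after median scaling, total scaling, cyclic loess, normexp with quantile and normexp with median scaling. Of these, 17, 47, 4, 0 and 1 were lower in FAK, against 18 of 52 after quantile normalization. The number of probes at an unadjusted p under 0.05 was 204, and became 85 for the values as deposited, 115 among the probes brighter than the median probe, 123 without the replicate block and 125 to 272 without 1 rat. The number of changed probes stayed at 1 with other pseudocounts, with that filter and with the rat as a random block. The whole-profile shift of 0.018 turned to -0.012 without rat 424, and ranged up to 0.036 without rat 425, and passed no test. For RG339 the 25 alternatives gave 0.85 to 1.49 on the log2 scale, with limma adjusted p from 2.11e-05 to 0.65 and 14 past the threshold. RG325 passed in 8, R344 in 5 and RG389 in 2 of their 25, with no change of direction in any of the 4. The alternatives are not independent. The passes of RG339 and RG325 include every fit without rat 425, most of them chosen after seeing the data. Those of RG339 also include the other pseudocounts and the filter, which keep the quantile normalization. The mean correlation of rat 425 with the other rats moved from -0.24 to -0.035 and -0.032 after normexp with quantile and with median scaling. Why these settings changed the results was not tested. The tests of the targeted gene and of the gene lists, with their alternatives, were not run because no probe is paired with a gene. The dim signal limits the rest: on the array with the lowest share, 17.9% of the probes exceeded 2 times the floor.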

Other observations

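The test of a relation between RG339 and the rest of the profile was chosen after the result was seen.

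Much of the variation lay between rats. After removal of the group means, a median of 68.4% of a probe's variance lay between rats, where 50% is expected for unrelated legs, and 891 of 1185 probes were above that share. Array properties shared by the legs of a rat, such as brightness, cannot be told apart from the animal here. The probe with the largest spread between rats was R630 (SD 1.77 on the log2 scale), which was picked for that spread. Its log2 level was 19.1 and 18.4 in the empty and FAK legs of rat 425, against 14.6 and 13.5 in rat 435. In rats 424, 426, 434 and 436 its level was 17.1, 16.4, 16.3 and 14.2 in the empty leg and 17.7, 17.7, 15.5 and 15.1 in the FAK leg. The FAK leg was higher in 3 rats and lower in 3.

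A hypothesis is that RG339 follows the size of the rest of the profile in each rat, measured as the slope of the rat's other probes on the mean of the other 5 rats. After quantile normalization, Pearson r over the 6 rats was 0.45 (exact permutation p = 0.39) and Spearman rho 0.32 (exact permutation p = 0.54). After scaling to the array median, r was 0.93 (exact permutation p = 0.0056, adjusted over 6 scalings 0.019) and rho 0.94 (exact permutation p = 0.017, adjusted 0.050). Total scaling and cyclic loess gave r of 0.94 and 0.92, and normexp gave 0.27 with quantile and 0.72 with median scaling. Without the 2 rats farthest from the median of RG339, r was 0.49 after quantile normalization, 0.66 after median scaling, where these were rats 425 and 426, and -0.25 after normexp with median scaling. The relation depends on the scaling and stays undecided. The scaling of an array acts on both measures, and the identity of RG339 is not known here.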
